A study of Escherichia coli with 9 samples.

How the data were processed

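The RNA sequenced was azide-labelled RNA pulled out of total RNA from E. coli K12 with streptavidin beads after 0, 5 or 10 min of chase, with 3 libraries per time. Libraries were made with a strand-preserving kit. The values used were FPKM (fragments scaled by gene length and by the mapped fragments of the library), computed by the authors and deposited as 1 table with a column per library. The submitters' processing notes name CASAVA 2.19, Trim Galore 0.6.5, HISAT2 2.1.0, SAMtools 1.3 and StringTie 2.1.4 and the build ASM584v2, without saying what each was used for. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap or lie opposite each other, and near-identical copies such as the ribosomal RNA operons, may therefore share reads.

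FPKM divides each gene by the sum over the library, in which ribosomal RNA took 69.6% to 78.6% of the fragments, so a loss of many messages raises the values of whatever is left. It also means that a value is the share of a gene among labelled RNA, not an amount per cell. Reads and depths were not given and could not be worked back from the values, so the precision of low values comes only from the spread between libraries. The table had 4470 named genes, of which 4205 were matched to the reference gene table by symbol, 197 by a synonym and 68 not at all. A further 60 values stood beside no gene name in the column of 5 min replicate 2 and were left out.

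Samples were grouped by the chase time in their labels. Replicate numbers were checked for pairing across times: for the 9 pairs of libraries with the same number, the correlation of deviations from the time mean ran from -0.0575 to 0.0726, and 2 of the 9 libraries correlated best with their own number. They were therefore not taken to pair samples. No pair of libraries held identical values.

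The main test was limma 3.58.1 in R 4.3.3 on log2 of FPKM plus a pseudocount of 1, for the 3774 genes with a mean of at least 1 FPKM over the 9 libraries. All 9 libraries entered 1 fit with a mean per time and a trend of variance on mean, tests were 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The pseudocount shrinks the change of genes near 1 FPKM. The comparisons were 5 against 0 min, 10 against 0 min, 10 against 5 min and a test over the 3 times. Shares of RNA classes were compared by an exact permutation test.

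Gene lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 32 lists of a comparison, and again with an estimated correlation, with which no list was called (lowest adjusted p 0.107, 0.0708 and 0.676 in the order of the comparisons above). The lists were ribosomal RNAs, transfer RNAs, housekeeping non-coding RNAs, regulatory small RNAs, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ATP synthase, NADH dehydrogenase I, terminal oxidases, glycolysis, TCA cycle, anaerobic respiration and fermentation, purine synthesis, nucleoside uptake and purine salvage, and pyrimidine synthesis. They went on with amino acid synthesis, tryptophanase and amino acid breakdown, carbon source uptake under CRP, outer membrane proteins and lipoproteins, fatty acid and phospholipid synthesis, heat shock proteins, cold shock proteins, the RpoS general stress response, the SOS response, the oxidative stress response, iron acquisition, flagella and chemotaxis, toxin-antitoxin systems, RNA degradation, RNA polymerase and sigma factors, and cell division and cell wall.

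Genes named in the text followed a rule: for 10 against 0 min the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 FPKM and no overlap between the times, for 5 against 0 min the 5 and 5, and for 10 against 5 min the 3 and 3, of which only 2 rises passed. From each list up to 4 members with the smallest p at 10 against 0 min were added, and rnpB, ssrA, ffs, ssrS, lpp, ompA, ompC, acpP, cspA, cspE, tufA, gapA, rpoB, rpoS, rne and pnp were always included. The tests, lists, this rule and the alternatives were fixed before the data were examined, apart from those said to be chosen later.

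The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 10 FPKM, quantile normalization, median centring, an anchor on the mean of the stable RNAs rnpB, ssrA, ffs and ssrS, leaving out ribosomal and transfer RNA genes and rescaling, a fit of only the 6 libraries compared, a replicate block, no trend, a log2 change of at least 1 as well, and leaving out each library in turn. An anchor on summed ribosomal RNA was added after seeing the data. The 10 against 0 min test was tested on simulated data, in 5 runs with 200 of 3774 genes changed. It recovered 9.85% of genes changed by 0.5 on the log2 scale, 75.2% at 1 and 96.7% at 2, with 7.8 false calls per run. In the data 3000 genes were called in this comparison, far more than the simulation changed. The simulated rates therefore need not hold for the real test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.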

Results

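Labelled RNA of Escherichia coli K12, a laboratory strain, was followed through a chase. Growing cells were given AzG, an azidonucleoside, at 100 µM for 2 h, so that RNA made in this time carried azide groups. The cells were then spun for 10 min and resuspended in nucleoside-free medium with 100 µM guanosine, which starts the chase. RNA was taken after 0, 5 or 10 min, its azide groups were joined to biotin with a DBCO reagent, and the biotinylated RNA was bound to streptavidin beads and sequenced, with 20 ng of RNA going into each library. Each chase time had 3 libraries, 9 in all. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. By the series title, the question is how stable each transcript is, read from how much of it is left among the labelled RNA. The authors' FPKM values for 4470 named genes were used, of which 3774 had a mean of at least 1 FPKM and were tested. FPKM sums ran from 456181 to 512931 per library, and since no read counts or depths were given, the depth is unknown and no counting interval can be stated. FPKM is a relative unit, and no spike-in or library without AzG was analysed here. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.980 to 0.986 between libraries of the same time and 0.901 to 0.920 between 0 and 10 min.

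Ribosomal RNA made up most of the labelled RNA at every time, and messages for proteins outside the ribosome took a falling share. Protein-coding genes other than those for ribosomal proteins, with the transfer-messenger RNA ssrA left out as well, took 25.0% ± 0.620 of the FPKM sum at 0 min, 17.8% ± 2.20 at 5 min and 13.8% ± 0.840 at 10 min (SD, n = 3 per time; exact permutation p = 0.00357, adjusted p = 0.00952). Besides 4005 genes annotated as protein-coding, this class held 61 genes not matched to the reference and 1 pseudogene. The RNA ssrA, which the deposited table files among these genes, took 3.07% ± 0.214, 2.75% ± 0.221 and 2.27% ± 0.236 and was not tested as a share. Genes for ribosomal proteins, the protein part of the ribosome, took 7.65% ± 0.551, 15.1% ± 2.22 and 14.4% ± 1.04 (exact permutation p = 0.025, adjusted p = 0.05, which is not under the threshold of 0.05). Ribosomal RNA took 60.4% ± 0.371, 60.4% ± 5.19 and 66.5% ± 2.28, a difference that did not pass (exact permutation p = 0.15, adjusted p = 0.192). Small and other non-coding RNAs fell from 1.76% ± 0.150 to 1.3% ± 0.119 and 0.956% ± 0.157 (exact permutation p = 0.00357, adjusted p = 0.00952), and transfer RNAs took 1.84% ± 0.126, 2.49% ± 0.434 and 1.89% ± 0.314 (exact permutation p = 0.0964, adjusted p = 0.154). The median FPKM of a gene, with RNA genes left out, fell from 9.41 ± 0.639 to 5.64 ± 0.866 and 4.01 ± 0.330 (exact permutation p = 0.00357, adjusted p = 0.00952). The tests covered 8 measures and used all 1680 assignments of the libraries to the 3 times, and 0.00357 is the smallest p they can give. They have no side, since times were compared by their spread. The FPKM sum itself (exact permutation p = 0.429) and the share of all genes outside the RNA classes (exact permutation p = 0.168) did not pass. The library of 5 min replicate 3 stood apart from the other 5 min libraries, with 66.3% ribosomal RNA against 56.4% and 58.6%, and 12.6% ribosomal protein messages against 16.9% and 15.8%.

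**Figure D1:**
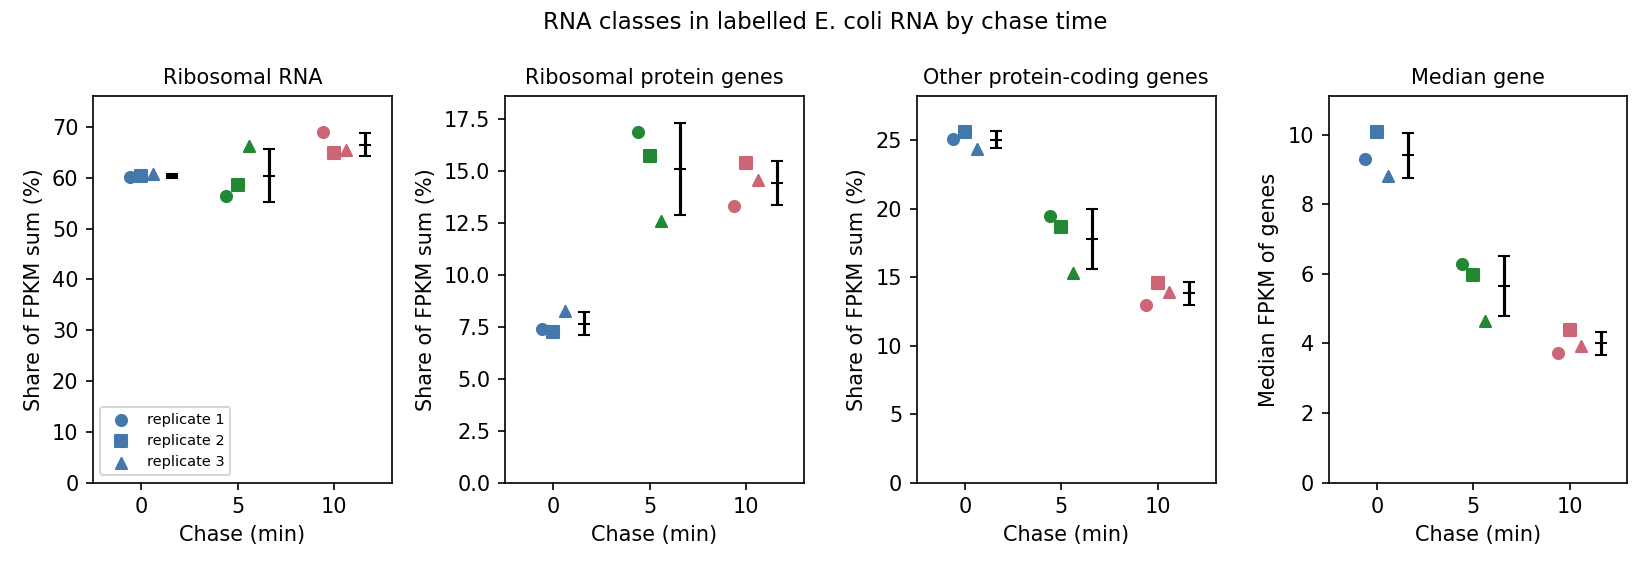
Share of the FPKM sum (%) taken by ribosomal RNA, ribosomal protein genes and other protein-coding genes, and the median FPKM of a gene, against chase time (min); symbols are the 3 libraries of a time and black bars the mean ± SD. Other protein-coding genes (with 61 genes not matched to the reference and 1 pseudogene) went from 25.0% to 13.8% and the median gene from 9.41 to 4.01 FPKM. Ribosomal protein genes stood at 7.65% at 0 min and 14.4% at 10 min.

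Over the whole chase, from 0 to 10 min, messages of 44 of 54 ribosomal protein genes and of sodA, the manganese superoxide dismutase, rose among the labelled RNA, while those of the 9 cold shock genes and of 31 of 35 genes for carbon source uptake fell. The set test called these 3 lists as deposited and none with an estimated correlation (adjusted p = 0.213, 0.498 and 0.836). The largest falls of single genes included gadA, gadB and gadC, known for acid resistance, and the hydrogenase genes hyaD, hyaE and hyaF, which were not tested as groups. The message of sodA (chromosome positions 4100810 to 4101430) went from 7.12 ± 0.719 to 63.8 ± 2.81 FPKM, a log2 change of 3.0 (SE 0.19, n = 3 per time, adjusted p = 9.17e-10). The message of gadC (1568954 to 1570489), the glutamate and GABA exchanger of acid resistance, went from 109 ± 19.9 to 1.45 ± 0.207 FPKM, a log2 change of -5.48 (SE 0.18, adjusted p = 9.73e-13). The message of cspB (1641339 to 1641554), a cold shock protein, went from 252 ± 16 to 5.10 ± 0.882 FPKM (log2 change -5.38, SE 0.25, adjusted p = 3.47e-11). The message of rplP (3448759 to 3449169), a protein of the large ribosomal subunit, went from 538 ± 67.7 to 1640 ± 209 FPKM (log2 change 1.61, SE 0.16, adjusted p = 2.50e-07). These positions and all others given are on the chromosome of E. coli K12 in the reference gene table, where these genes are annotated as protein-coding, and the build named in the submitters' processing notes is ASM584v2.

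The other large rises were in yoeI (log2 change 2.49), a short gene that overlaps plaP, in plaP itself (2.26), a putrescine importer, and in ndk (2.18), nucleoside diphosphate kinase. They were followed by osmB (2.01), an osmotically inducible lipoprotein, yiaD (1.76), cbrB (1.54) and the ribosomal protein genes rplV (1.58) and rpsR (1.54), with SE from 0.16 to 0.25. The gene plaP rose from 26.6 ± 2.39 to 132 ± 19.4 FPKM and osmB from 65.9 ± 5.87 to 268 ± 17.7 FPKM. The other large falls were in the hydrogenase genes hyaF (-5.12), hyaE (-4.62) and hyaD (-4.38) and in gadA (-4.84) and gadB (-4.68), the glutamate decarboxylases. They were followed by yhiD (-4.59), cspI (-4.42) and lacZ (-4.40), beta-galactosidase, with SE from 0.18 to 0.37. The message of lacZ (363231 to 366305) went from 328 ± 44.9 to 14.5 ± 1.94 FPKM and that of hyaF from 71.2 ± 16 to 1.05 ± 0.288 FPKM. These 10 rises and 10 falls were past the threshold under each of the other scalings. The pairs gadA and gadB, and members of the csp family, are alike in sequence, so how their shared reads were placed bears on these values, and yoeI and plaP cannot be told apart where they overlap.

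In total, 3000 of the 3774 genes (79.5%) were called between 0 and 10 min, 172 higher and 2828 lower on the deposited scale. Of these, 58 rose and 1597 fell by at least 2-fold. The groups of 3 libraries did not overlap for 3088 genes (81.8%), where chance gives 10%. The median gene stood at -0.89 on the log2 scale, so values relative to the median gene are given as well. The split depends on the scale: with the stable RNA anchor (the mean log2 value of rnpB, ssrA, ffs and ssrS held level, not each of them) the median gene stood at 0.31 and 1086 genes were higher and 374 lower, with median centring at 0.18 with 1174 and 619, with quantile normalization at 0.05 with 856 and 724, and with ribosomal and transfer RNA genes left out at -0.66. With the ribosomal RNA anchor, chosen after seeing the data, it stood at -0.98 with 143 higher and 2978 lower. The 4 RNAs of the stable RNA anchor did not move alike as deposited, with quartiles of -1.53 and -0.76. Their mean of -1.19 lay below the median gene, which is why that gene stood above 0 with this anchor.

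Of 54 ribosomal protein genes, 44 rose and 10 did not pass, with rplP, rplV, rpsS (593 ± 85.3 to 1703 ± 126 FPKM) and rpsR among them. Their median log2 change was 0.82, 1.70 above the median gene, and it stayed above 0 under the other scalings, the lowest being 0.39 with quantile normalization. The set test called the list higher than other genes (adjusted p = 2.23e-76; adjusted p = 0.213 with an estimated correlation). Of 15 genes of the TCA cycle, the oxidative route from acetyl-CoA, 6 rose, 5 did not pass, and sucA, sucB, sucC and acnA fell, though each stood above 0 with the stable RNA anchor, median centring and quantile normalization. Among the risen were icd (62.1 ± 0.724 to 137 ± 11.3 FPKM), isocitrate dehydrogenase, and sdhA and sdhD of succinate dehydrogenase (log2 changes 1.24 and 1.15). The median of the list was 0.19, 1.08 above the median gene and above 0 under each scaling (adjusted p = 9.92e-09; adjusted p = 0.498 with an estimated correlation). Of 28 iron acquisition genes, 9 rose and 3 fell, or 8 and 3 adjusted over the list alone, with exbB (15.9 ± 3.58 to 36.5 ± 3.75 FPKM) and exbD, which pass energy to outer membrane transporters. The enterobactin genes entC (log2 change 1.04) and entS (0.98) rose as well, at up to 2.71 ± 0.270 and 3.26 ± 0.173 FPKM. That list had a median of 0.06, which was -0.03 with the ribosomal RNA anchor (adjusted p = 2.39e-13; adjusted p = 0.382 with an estimated correlation). Counts adjusted over the list alone differed from those over all tested genes for 5 lists in this comparison, and both are given there.

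Some lists were called higher than other genes although their own values were near or below 0. Of 22 ribosomal RNA genes, 2 rose and 4 fell (0 and 3 adjusted over the list alone), with a median of 0.03 and a mean of -0.12. The set test called them (adjusted p = 1.09e-06; adjusted p = 0.0708 with an estimated correlation), and quantile normalization ended this call. Of 83 transfer RNA genes, 4 rose and 24 fell (3 and 19 adjusted over the list alone), among them metY (58.2 ± 9.54 to 22.8 ± 3.86 FPKM). Their median was -0.19, or 1.01 with the stable RNA anchor (adjusted p = 5.74e-09; adjusted p = 0.812 with an estimated correlation). Of 13 translation factor genes, 3 rose, among them tsf (log2 change 0.59), an elongation factor, and 3 fell, among them prfA (-1.60), a release factor. That median was -0.10, or 1.1 with the stable RNA anchor (adjusted p = 0.000491; adjusted p = 0.884 with an estimated correlation), and quantile normalization ended the call. Of 12 pyrimidine synthesis genes, 2 rose and 5 fell, among them pyrB (-1.51), aspartate carbamoyltransferase. Their median was -0.28, or 0.91 with the stable RNA anchor (adjusted p = 0.0372; adjusted p = 0.884 with an estimated correlation). The pyrimidine call ended without 0 min replicate 1 or 2 and without 10 min replicate 2 or 3, with an adjusted p of up to 0.079, and with a filter at a mean of 10 FPKM. Copies of the ribosomal RNA operons and of transfer RNA genes are nearly identical, and how shared reads were placed is not given in the sources used here.

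Lists for oxygen limitation, cold and sugar use were called lower, and their medians stayed below 0 under each scaling. Of 28 genes of anaerobic respiration and fermentation, 27 fell and napF did not pass. Their median was -2.55, at -1.66 relative to the median gene (adjusted p = 5.52e-06; adjusted p = 0.715 with an estimated correlation). Among them pflB, pyruvate formate-lyase, went from 688 ± 113 to 80.0 ± 3.85 FPKM and adhE, the fermentative alcohol dehydrogenase, from 212 ± 57.5 to 16.6 ± 1.02 FPKM. The hydrogenase genes hyaA and hyaB changed by -3.74 and -4.15. The 9 cold shock genes fell, with a median of -2.49, at -1.61 relative to the median gene (adjusted p = 0.000184; adjusted p = 0.498 with an estimated correlation). The message of cspA went from 4357 ± 426 to 267 ± 52.5 FPKM, and cspG and cspE changed by -3.80 and -2.49. Of 35 genes for carbon source uptake under CRP, the regulator that acts with cyclic AMP, 31 fell, or 32 adjusted over the list alone. Their median was -2.32 (adjusted p = 3.18e-05; adjusted p = 0.836 with an estimated correlation), and lacZ and the mannose transporter genes manX, manY and manZ (-4.26, -4.03 and -3.98) were among them. The 19 heat shock genes fell, with a median of -1.53 (adjusted p = 0.000953; adjusted p = 0.884 with an estimated correlation). Among them were the chaperone genes dnaK (127 ± 26.9 to 18.1 ± 2.32 FPKM), dnaJ (-2.42) and htpG (-2.26) and the protease gene hslV (-2.09). Of 12 glycolysis genes, 11 fell, with a median of -1.41 (adjusted p = 0.00645; adjusted p = 0.884 with an estimated correlation). Among them were gapA (1069 ± 111 to 211 ± 13.6 FPKM), pgk (-2.30), pykA (-2.40) and fbaA (-2.14).

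Another 3 lists had medians below 0 under each scaling but were not called by the set test on the deposited scale. Of 21 genes for tryptophanase and amino acid breakdown, 15 fell and 1 rose, with a median of -2.32 (adjusted p = 0.185; called without 0 min replicate 3, at -1.62 relative to the median gene). Among the fallen were gcvP (-2.63), of glycine cleavage, and cadB (-3.14), the lysine and cadaverine exchanger. Of 29 genes of the general stress response under RpoS, the stationary phase sigma factor, 25 fell and 2 rose, with a median of -1.39 (adjusted p = 0.222). The message of hdeA, an acid chaperone, went from 813 ± 115 to 130 ± 22.7 FPKM, hdeD and gadX changed by -3.54 and -3.36, and osmB rose. Both lists were called lower under the stable RNA anchor, median centring, quantile normalization and a filter at a mean of 10 FPKM. Of 18 RNA degradation genes, 17 fell and 1 rose, with a median of -1.24 that was -0.04 with the stable RNA anchor (adjusted p = 0.149; called with no filter and with ribosomal and transfer RNA genes left out). Among them were rne, ribonuclease E, from 63.5 ± 4.53 to 17.4 ± 2.04 FPKM, hfq (-1.77), the small RNA chaperone, and rhlB (-1.64), a helicase whose call the stable RNA anchor ended.

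For the remaining 17 lists, no call was made by the set test, with adjusted p from 0.0569 for cell division to 0.858 for outer membrane proteins. Their medians were below 0 as deposited and above 0 with the stable RNA anchor, so the falls given next belong to the deposited scale. All 4 housekeeping non-coding RNAs fell, with a median of -1.10 against 0.09 with the anchor they define. Of 27 regulatory small RNAs, 21 fell and 1 rose (median -0.80, or 0.39 with the anchor), with gadY at -3.26 and csrC at -1.61. Of 23 aminoacyl-tRNA synthetase genes, 15 fell (-0.58, or 0.62), with lysU at -1.97 and thrS at -1.50, and of 9 ATP synthase genes, 3 fell (-0.26, or 0.93). The 13 genes of NADH dehydrogenase I fell (-0.84, or 0.35). The terminal oxidases parted: cydA, cydB and cydX of the high-affinity bd oxidase fell (-2.38, -2.35 and -2.43), while cyoD of the bo oxidase rose (29.3 ± 15.6 to 60.3 ± 11.9 FPKM), in all 4 lower and 3 higher of 8 (-0.18, or 1.02). Of 15 purine synthesis genes, 12 fell (-0.95, or 0.25), with purC at -2.60, and of 16 genes for nucleoside uptake and purine salvage, 14 fell and 1 rose (-1.13, or 0.06), with deoA at -2.15 and udp at -1.83. Of 55 amino acid synthesis genes, 41 fell and 2 rose, or 40 and 2 adjusted over the list alone (-0.97, or 0.22), with serC at -2.05, hisD at -1.98, and the risen argD (0.85) and argG (0.64). Without 0 min replicate 1, argG was no longer called, at 0.52 (adjusted p = 0.053, the highest over all alternatives).

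Of 19 genes for outer membrane proteins and lipoproteins, 14 fell and 1 rose (median -0.84 as deposited, or 0.36 with the stable RNA anchor), with ompW at -3.38, and of 20 genes for fatty acid and phospholipid synthesis, 15 fell (-0.77, or 0.42), with fabB at -2.22 and fabA at -1.72. Of 22 SOS response genes, 21 fell (-0.90, or 0.29 with that anchor), with sulA, a cell division inhibitor, at -1.31 and lexA, the repressor, at -1.26. Of 17 oxidative stress genes, 11 fell and 1, sodA, rose (-1.04, or 0.15), with ahpF at -2.13 and grxA at -1.79. Of 11 tested flagella and chemotaxis genes, 8 fell (-0.72, or 0.47), with flgM at -1.56. Of 31 toxin-antitoxin genes, 26 fell (-0.89, or 0.30), with hha at -2.53 and tomB at -2.34. Of 17 genes for RNA polymerase and sigma factors, 10 fell and 2 rose (-0.61, or 0.58), with rpoE, the envelope stress sigma factor, at -3.07 and rho, the termination factor, at -1.91. Of 31 cell division and cell wall genes, 30 fell (-1.02, or 0.17), with ftsW at -1.57 and murC at -1.55. The stable RNA anchor ended the calls of csrC, thrS, sulA, lexA, flgM, ftsW, murC, metY, prfA, pyrB, pyrI and ssrS. Median centring ended those of lexA, metY, flgM, pyrI and ssrS, and quantile normalization those of metY, flgM and pyrI. The set test compares a list with other genes, and it pointed up, without a call, for small RNAs, synthetases, ATP synthase, terminal oxidases, oxidative stress, flagella and RNA polymerase, whose medians and means were below 0. Cell division was called lower without 5 min replicate 3 (-0.14 relative to the median gene), with only the 6 libraries compared, a replicate block, a pseudocount of 0.1, no filter, and ribosomal and transfer RNA genes left out. Terminal oxidases were called higher without 0 min replicate 3 (0.97), flagella with no filter, ATP synthase with the stable RNA anchor, median centring and quantile normalization, and synthetases with the last pair.

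Where 5 or fewer members of a list moved between 0 and 10 min, they were the following, chosen after their values were seen unless the rule for named genes took them. The risen were rrsE and rrlE among ribosomal RNAs, glyT, alaT, alaV and thrT among transfer RNAs, tsf, fusA and tufB among translation factors, cyoC, cyoD and cyoE among terminal oxidases, and pyrF and upp in pyrimidine synthesis. They also included cyaR, a small RNA, gpt, of purine salvage, putA, of proline breakdown, ompX, an outer membrane protein, osmY, rph, ribonuclease PH, and rpoA and rpoC of RNA polymerase. The fallen were rrfA, rrfB, rrfE and rrfG, copies of 5S ribosomal RNA, the translation factors prfA, lepA and prfB, atpB, atpC and atpI of ATP synthase, cyoA, the pyrimidine genes codA, codB, pyrB, pyrC and pyrI, and fhuE and feoB, of iron uptake, and sufS, of iron-sulfur cluster assembly. With the stable RNA anchor and with median centring each of these falls but prfA, pyrB and pyrI turned to a value above 0 (sucA at 0.67 and 0.54, feoB at 0.67 and 0.54), and with quantile normalization fusA and rpoA stood just below 0. Leaving out 1 library ended calls among rrsE, rrlE, alaT, fusA, tufB, cyoC, cyoE, pyrF, gpt, rph, rpoC, rrfE, atpB, atpC, cyoA, sucA, sucC, fhuE, sufS and feoB. Each of the 6 libraries of 0 and 10 min did so for some of them, as did 5 min replicates 2 and 3 for rrsE and rrfE, with values such as 0.26 for rrsE without 0 min replicate 2 and -0.44 for rrfE without 10 min replicate 1 (adjusted p = 0.206, the highest).

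Single RNAs chosen in advance, among them non-coding RNAs and messages of common proteins, showed how far direction rests on the scale. The RNA of ribonuclease P, rnpB, went from 3361 ± 336 to 1872 ± 377 FPKM (log2 change -0.86, adjusted p = 9.12e-05), but stood at 0.21 with median centring and 0.34 with the stable RNA anchor. The transfer-messenger RNA ssrA changed by -0.48, with 0.59 and 0.71 under those scalings. The RNAs ssrS (-1.34) and ffs (-2.09), the latter at 11.2 ± 2.79 FPKM at 0 min, fell as deposited. Of the RNAs in the stable RNA anchor, ffs fell furthest and so lowers their mean. No stable RNA anchor without ffs was tried, so values with this anchor rest in part on that RNA. The lipoprotein message lpp (-0.72, or 0.35 and 0.47) and the porin message ompC (-0.84, or 0.23 and 0.36) fell only on part of the scales, as did rpoS (-0.72, or 0.35 and 0.47) and pnp (-0.49, or 0.58 and 0.71). No change was called as deposited for ompA (822 ± 22.0 to 874 ± 74.6 FPKM, log2 change 0.09), tufA (0.27), acpP (-0.32) and rpoB (-0.05). The gene tufA, still at 0.27, was called with only the 6 libraries compared (adjusted p = 0.0266) and without 5 min replicate 3 (adjusted p = 0.0165). Quantile normalization ended the calls of ffs, ssrA and rpoS, and leaving out ribosomal and transfer RNA genes those of ssrA and lpp. With the stable RNA anchor ompA, tufA, acpP and rpoB stood at 1.28, 1.47, 0.87 and 1.14, and with quantile normalization ompA and tufA stood at -0.44 and -0.32.

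**Figure D2:**
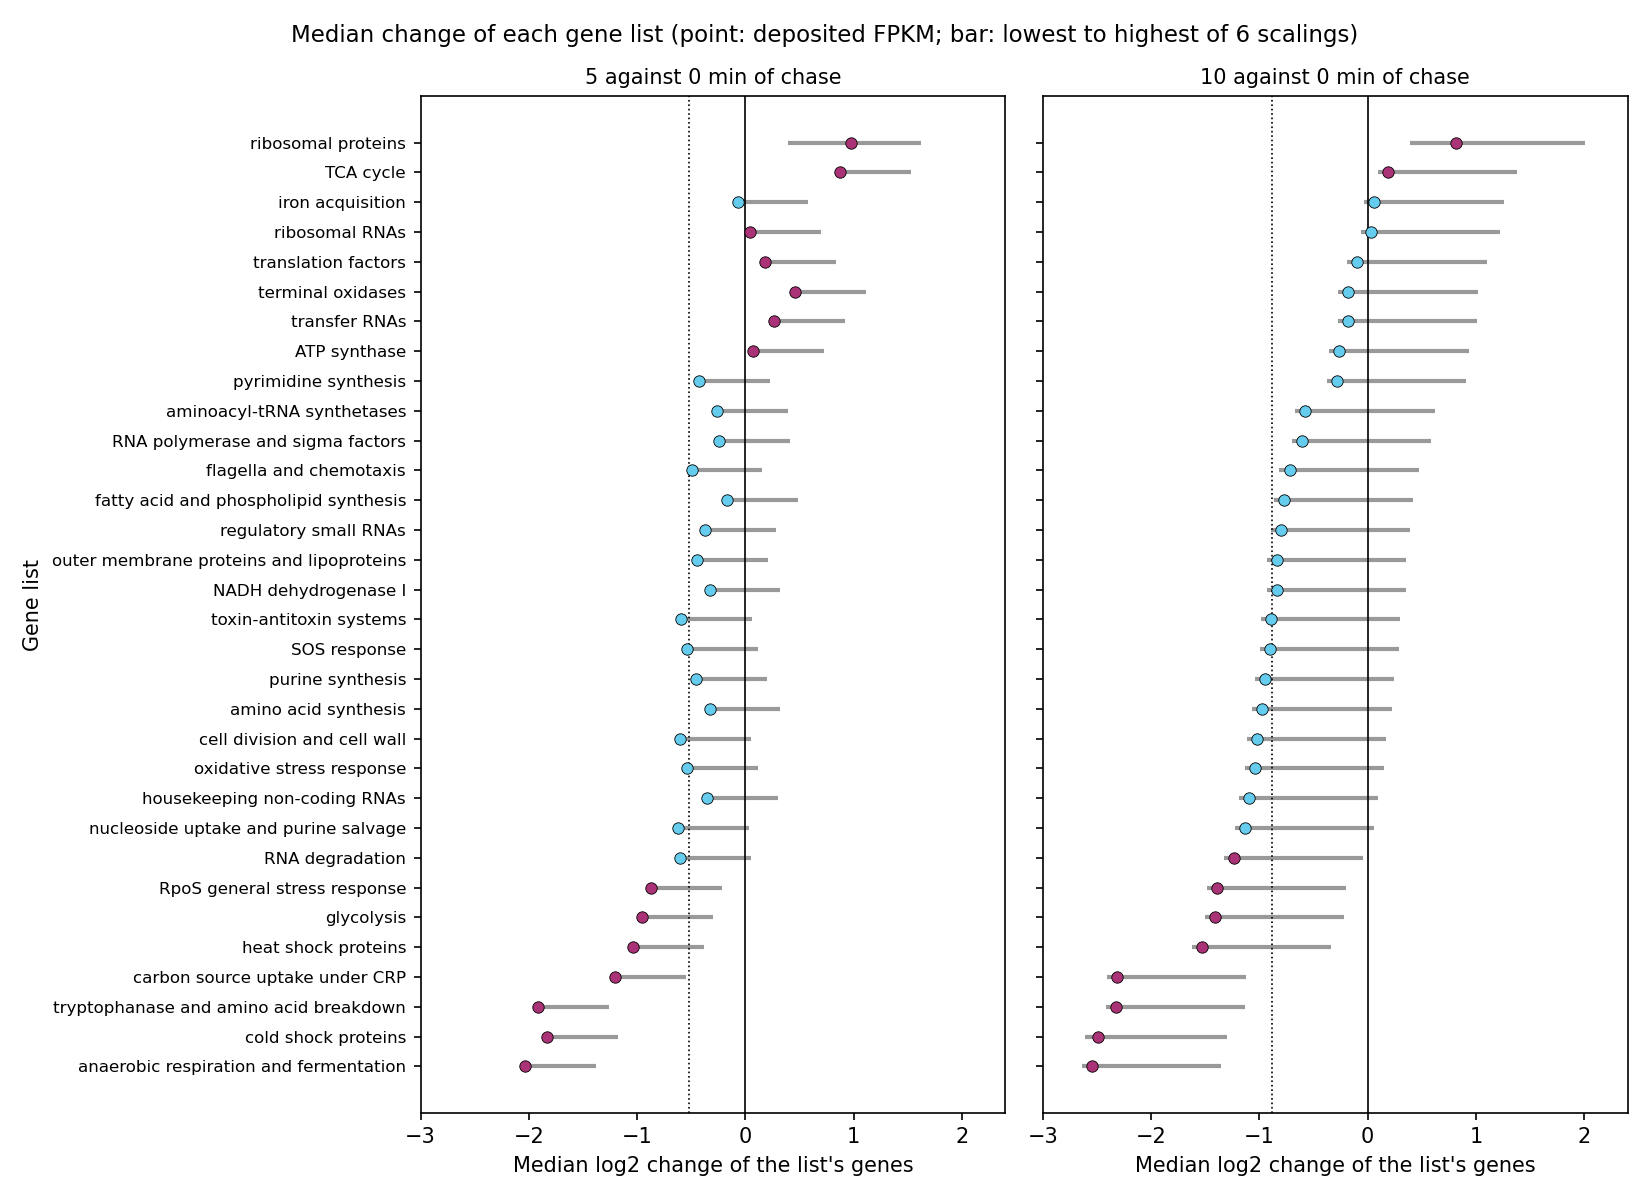
Median log2 change of the tested members of each gene list (horizontal axis, log2 FPKM + 1) for 5 and for 10 against 0 min, with grey bars from the lowest to the highest median over 6 scalings and a dotted line at the median of all tested genes. Purple points mark lists whose median keeps its sign under the 6 scalings (ribosomal proteins from 0.39 to 2.01 between 0 and 10 min), and light blue points those whose median changes sign with the scaling (SOS response from -1.0 to 0.29 over the same time).

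**Figure D3:**
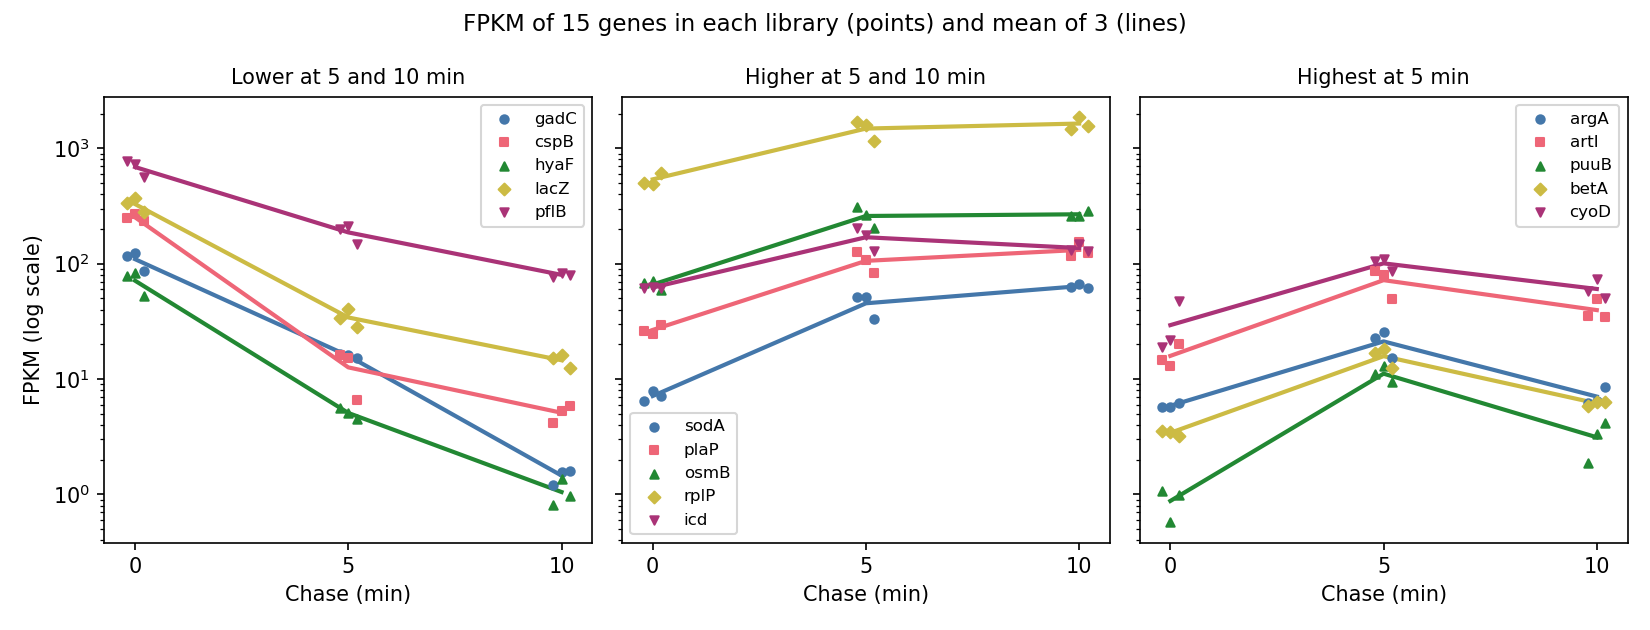
FPKM of single genes (log axis) against chase time (min), with points for the 3 libraries of a time and lines through their mean. The message of gadC went from 109 to 1.45 FPKM and that of sodA from 7.12 to 63.8 FPKM between 0 and 10 min, while argA stood at 5.86, 21.2 and 7.04 FPKM at 0, 5 and 10 min.

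In the first part of the chase, from 0 to 5 min, messages of 9 of 15 TCA cycle genes and of the single genes artI and artP rose, and those of the 9 cold shock genes and of the single genes hyaC, hyaE, hyaF and lacZ fell. The set test called both lists as deposited (adjusted p = 8.30e-10 and 0.000326) and neither with an estimated correlation (adjusted p = 0.457 for each). The message of artI (902257 to 902988), the binding protein of an arginine transporter, went from 15.9 ± 3.65 to 71.9 ± 20.0 FPKM, a log2 change of 2.09 (SE 0.23, n = 3 per time, adjusted p = 1.07e-06), and artP of the same transporter changed by 2.05 (SE 0.20). The message of sodA went from 7.12 ± 0.719 to 45.3 ± 10.7 FPKM (log2 change 2.49, SE 0.19), and yoeI (2.31) and ndk (2.18) rose too. The message of cspB went from 252 ± 16 to 12.6 ± 5.20 FPKM (-4.30, SE 0.25, adjusted p = 3.51e-09), and hyaC (-3.74), yhiD (-3.64), hyaE (-3.61), hyaF (-3.55) and lacZ (-3.23) fell. In this comparison 2135 of 3774 genes (56.6%) were called, 253 higher and 1882 lower, with a median gene at -0.52. The groups did not overlap for 2376 genes (63.0%, where chance gives 10%). The median gene stood at -0.07 with the stable RNA anchor (456 higher, 557 lower), at 0.13 with median centring (954 and 523) and at 0.03 with quantile normalization (687 and 641).

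Of the ribosomal protein genes, 50 of 54 rose by 5 min (53 adjusted over the list alone), among them rpsS (1.54), rplV (1.53) and rplP (1.45). Their median was 0.97, lowest at 0.40 with quantile normalization (adjusted p = 5.35e-62; adjusted p = 0.334 with an estimated correlation). Of the TCA cycle genes, 9 of 15 rose, as many adjusted over the list alone, with icd at 1.41. Their median was 0.87 (adjusted p = 8.30e-10; adjusted p = 0.457 with an estimated correlation). Transfer RNAs rose in 26 and fell in 8 of 83 (24 and 8 adjusted over the list alone). Their median was 0.26 (adjusted p = 1.90e-16; adjusted p = 0.457 with an estimated correlation). Ribosomal RNAs rose in 3 of 22 (2 adjusted over the list alone), with a median of 0.04 (adjusted p = 7.93e-06; adjusted p = 0.107 with an estimated correlation). Translation factors rose in 3 and fell in 2 of 13 (2 and 1 adjusted over the list alone), with a median of 0.18. That call (adjusted p = 0.000941; adjusted p = 0.813 with an estimated correlation) ended with quantile normalization.

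For some lists the set test and the members pointed apart at 5 min. Of 9 ATP synthase genes, 1 fell, or 0 adjusted over the list alone, and the median was 0.07. The set test called the list higher than other genes (adjusted p = 0.0288; adjusted p = 0.813 with an estimated correlation). That call ended without 0 min replicate 1 or 2 or 5 min replicate 2, with an adjusted p of up to 0.0779, and with a filter at a mean of 10 FPKM. Iron acquisition genes rose in 5 and fell in 4 of 28 (4 and 3 adjusted over the list alone), with a mean of 0.01 and a median of -0.07 that was 0.58 with median centring. They were called higher than other genes (adjusted p = 0.000228; adjusted p = 0.813 with an estimated correlation). Amino acid synthesis genes fell in 23 and rose in 9 of 55 (24 and 9 adjusted over the list alone), with a mean of -0.13 and a median of -0.33 that was 0.32 with median centring. This list too was called higher than other genes (adjusted p = 0.00585; adjusted p = 0.813 with an estimated correlation). Of the risen members 8 were arginine synthesis genes, among them argD (14.2 ± 5.71 to 50.6 ± 10.4 FPKM), argC (1.70), argA (1.66) and argG (1.61), chosen after their values were seen. In the terminal oxidases 4 rose and 3 fell of 8, the same adjusted over the list alone, with cyoD at 1.85 and cydA at -1.77. The set test made no call there (adjusted p = 0.0602). It did without 0 min replicate 3 (median 1.25 above the median gene), without 5 min replicate 1 (1.0), with only the 6 libraries compared and with the ribosomal RNA anchor.

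Lists for oxygen limitation, sugar use, cold, heat and amino acid breakdown were called lower by 5 min, with medians below 0 under each scaling. Anaerobic respiration and fermentation genes fell in 26 of 28, as many adjusted over the list alone. Their median was -2.03 (adjusted p = 1.24e-09; adjusted p = 0.457 with an estimated correlation). Genes for carbon source uptake under CRP fell in 29 of 35, as many adjusted over the list alone. Their median was -1.20 (adjusted p = 5.47e-07; adjusted p = 0.661 with an estimated correlation). The 9 cold shock genes fell, as they did adjusted over the list alone, with a median of -1.83 (adjusted p = 0.000326; adjusted p = 0.457 with an estimated correlation). Heat shock genes fell in 18 of 19, as many adjusted over the list alone, with a median of -1.04 (adjusted p = 0.0027; adjusted p = 0.813 with an estimated correlation). Glycolysis genes fell in 11 of 12, as many adjusted over the list alone, with a median of -0.95 (adjusted p = 0.00729; adjusted p = 0.813 with an estimated correlation). Tryptophanase and amino acid breakdown genes fell in 15 and rose in 2 of 21, as many adjusted over the list alone, with a median of -1.92 (adjusted p = 0.0391; adjusted p = 0.813 with an estimated correlation). This call ended without 5 min replicate 3 (adjusted p = 0.0971), with a pseudocount of 0.1, with no filter on low values and with ribosomal and transfer RNA genes left out (adjusted p = 0.249, the highest apart from the estimated correlation). With a replicate block, 5 lists were called lower by 5 min in place of 6.

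Where 5 or fewer members of these lists moved by 5 min, they were the following, chosen after their values were seen. The ribosomal RNAs rrsE, rrlE and rrfD, the translation factors tsf, fusA and tufB, the oxidase genes cyoB, cyoC, cyoD and cyoE, the iron genes fepB, fepC, entS, exbB and exbD, and putA and dadX rose. The translation factors prfA and lepA, atpI of ATP synthase, the oxidase genes cydA, cydB and cydX, and the iron list members fhuC, sufS, feoA and feoB fell. Of these, lepA, atpI, feoB and fhuC stood above 0 with median centring (0.20, 0.19, 0.10 and 0.10), and fusA and tufB below 0 with quantile normalization (-0.13 and -0.035). Leaving out 1 library of 0 or 5 min, any of the 6, ended calls among rrfD, tsf, fusA, tufB, lepA, atpI, fepB, fepC, entS, fhuC, feoB and dadX, and so did 10 min replicates 1 and 3 for fhuC, 1 for dadX and 3 for lepA (adjusted p of up to 0.188, for dadX at 0.37 without 0 min replicate 1).

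In the second part of the chase, from 5 to 10 min, messages of gadC and gadB fell further, 36 of 55 amino acid synthesis genes fell, and 12 genes in all rose on the deposited scale. The median of the amino acid synthesis list was -0.77 as deposited and -0.03 with the stable RNA anchor, and its set test was not called with an estimated correlation (adjusted p = 0.75). The message of gadC went from 15.9 ± 0.660 to 1.45 ± 0.207 FPKM, a log2 change of -2.78 (SE 0.18, n = 3 per time, adjusted p = 7.53e-08), and gadB from 22.0 ± 4.59 to 4.17 ± 0.880 FPKM (-2.15, SE 0.20). The message of rdlC, a small antitoxin RNA, went from 12.3 ± 4.54 to 3.51 ± 3.04 FPKM (-1.90, SE 0.50, adjusted p = 0.0151). The message of metK (3086706 to 3087860), S-adenosylmethionine synthetase, went from 47.3 ± 8.65 to 69.7 ± 6.24 FPKM (0.56, SE 0.17, adjusted p = 0.0277). That of uraA, the uracil transporter, went from 9.84 ± 2.51 to 15.1 ± 0.666 FPKM (0.60, SE 0.20, adjusted p = 0.0367). These are the only rises that met the rule for named genes, and both rest on few libraries. The gene metK was no longer called without 5 min replicate 2 or any single 10 min replicate (0.49 to 0.60, adjusted p up to 0.0738). The gene uraA was no longer called without 0 min replicate 1, 5 min replicate 2 or 3, or any single 10 min replicate (0.42 to 0.63, adjusted p up to 0.102). The call of rdlC, which has near-identical copies, ended without 5 min replicate 1 or 2 (-1.74 and -1.73), and leaving out single libraries moved its value from -1.02, without 10 min replicate 3, to -2.36, without 10 min replicate 1. It also ended with quantile normalization, median centring and ribosomal and transfer RNA genes left out, and those of metK and uraA with only the 6 libraries compared and with the ribosomal RNA anchor.

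From 5 to 10 min, 851 of 3774 genes were called, 12 higher and 839 lower, and 1525 had an unadjusted p under 0.05. The groups did not overlap for 1418 genes (37.6%, where chance gives 10%). The count rests on single libraries, with 276 genes without 5 min replicate 1, 290 without 5 min replicate 2, 1769 without 5 min replicate 3, 339 without 10 min replicate 1 and 382 without 10 min replicate 3. The 12 higher calls became 2 without 10 min replicate 3, 5 without 5 min replicate 2, 9 without 5 min replicate 1, and 8 without 5 min replicate 3, 10 min replicate 1 or 10 min replicate 2. Direction also depends on the scale: the median gene stood at -0.37 as deposited, at 0.37 with the stable RNA anchor (340 higher and 26 lower), at 0.04 with median centring (97 and 140), at 0.01 with quantile normalization (82 and 122) and at -0.13 with ribosomal and transfer RNA genes left out (65 and 365).

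Amino acid synthesis genes fell in 36 of 55 from 5 to 10 min (44 adjusted over the list alone), among them hisC (-1.46) and hisD (-1.36, a call the stable RNA anchor ended). Their median was -0.77, or -0.03 with the stable RNA anchor (adjusted p = 4.57e-10; adjusted p = 0.75 with an estimated correlation). Cold shock genes fell in 5 of 9 (8 adjusted over the list alone), namely cspA, cspB, cspC, cspG and cspE, with cspE from 606 ± 119 to 181 ± 32.1 FPKM. Their median was -0.99, or -0.25 with the stable RNA anchor (adjusted p = 0.000559; adjusted p = 0.75 with an estimated correlation). Iron acquisition genes had a median of 0.17, above 0 under each scaling, with fepA and entB, 2 of 28, risen, or 0 adjusted over the list alone. The set test called them (adjusted p = 3.31e-17; adjusted p = 0.676 with an estimated correlation). The calls of cspA, cspB, cspC and cspG ended with the stable RNA anchor, and that of cspC without 5 min replicate 2 (-0.72). The call of fepA ended without 5 min replicate 1 or 10 min replicate 1 or 3 (0.71, 0.72 and 0.78) and that of entB without 5 min replicate 2 or 3 or 10 min replicate 1 or 3 (0.62 to 0.89).

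For the other lists called from 5 to 10 min the sign of the median changed with the scaling. Terminal oxidases fell in 8 of 8, also adjusted over the list alone, with a median of -0.72, or 0.02 with the stable RNA anchor (adjusted p = 0.00539; adjusted p = 0.838 with an estimated correlation). Heat shock genes fell in 11 of 19 (16 adjusted over the list alone), with a median of -0.57, or 0.17 with that anchor (adjusted p = 0.0059; adjusted p = 0.915 with an estimated correlation). Glycolysis genes fell in 6 of 12 (8 adjusted over the list alone), at -0.58, or 0.16 (adjusted p = 0.0116; adjusted p = 0.915 with an estimated correlation). Fatty acid and phospholipid synthesis genes fell in 11 of 20 (15 adjusted over the list alone), at -0.50, or 0.24 (adjusted p = 0.00539; adjusted p = 0.915 with an estimated correlation). Cell division and cell wall genes fell in 13 of 31 (20 adjusted over the list alone), at -0.51, or 0.23 (adjusted p = 0.00539; adjusted p = 0.915 with an estimated correlation). RNA degradation genes fell in 8 of 18 (10 adjusted over the list alone), at -0.52, or 0.23 (adjusted p = 0.0141; adjusted p = 0.915 with an estimated correlation). Their call ended without 5 min replicate 2 (-0.11 relative to the median gene).

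Ribosomal lists and pyrimidine synthesis were called higher than other genes from 5 to 10 min, with medians near or below 0. Ribosomal proteins fell in 1 of 54, rpsO, or 0 adjusted over the list alone, with a median of -0.15, or 0.59 with the stable RNA anchor (adjusted p = 0.000559; adjusted p = 0.915 with an estimated correlation). Without 5 min replicate 3 the test pointed down with no call, the list being 0.16 above the median gene. Ribosomal RNAs fell in 4 of 22 (rrfA, rrfB, rrfF and rrfG), also adjusted over the list alone, at -0.15, or 0.59 (adjusted p = 0.0414; adjusted p = 0.75 with an estimated correlation). Their call ended without 0 min replicate 1 or 3, 5 min replicate 1 or 2, or 10 min replicate 1, with an adjusted p of up to 0.205, and also with no filter, quantile normalization, median centring, the ribosomal RNA anchor and only the 6 libraries compared. Pyrimidine synthesis genes fell in 1 of 12, codB, or 0 adjusted over the list alone, at 0.02 with a mean just below 0, or -0.05 with the ribosomal RNA anchor (adjusted p = 0.000371; adjusted p = 0.75 with an estimated correlation). With the stable RNA anchor rpsO and codB stood at 0.24 and 0.19, and the single calls of these genes and of rrfA, rrfB, rrfF and rrfG, chosen after their values were seen, each ended without at least 1 of the libraries of 5 and 10 min (adjusted p of up to 0.181, for codB at -0.46 without 5 min replicate 1). A filter at a mean of 10 FPKM ended the calls of terminal oxidases, heat shock, glycolysis, fatty acid synthesis, cell division and RNA degradation. Quantile normalization ended those of terminal oxidases, glycolysis, fatty acid synthesis, cell division, RNA degradation and both ribosomal lists, and the stable RNA anchor those of glycolysis, fatty acid synthesis, cell division and RNA degradation. Other lists gained calls under some settings. As deposited 4 lists were called higher and 8 lower, and with the filter at 10 FPKM 5 and 5. The stable RNA anchor gave 6 and 7, and leaving out 5 min replicate 3 gave 4 and 13.

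Early and late calls against 0 min fell largely on the same genes. Of the genes called at 5 and at 10 min against 0 min, 2019 were called in both with the same sign, 156 higher, such as sodA, ndk and rplP, and 1863 lower, such as cspB, lacZ and hyaF. Independent lists of these lengths would share 11.5 and 1410. Simulated unchanged groups that share the 0 min libraries gave 4.04 on average, but most of them had no gene called in both. They therefore do not show how far the shared libraries raise the overlap of lists this long. A test over the 3 times called 2923 genes (77.5%). Across genes, the change from 0 to 5 min had a Pearson r of 0.0938 and a Spearman rho of 0.0875 with the change from 5 to 10 min, with a covariance of 0.0214. Since the 5 min libraries enter both with opposite sign, 100 simulated unchanged groups gave an r of -0.508 on average (-0.907 to 0.158), a rho of -0.483 and a covariance of -0.0253.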

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

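The genes and lists in this part were tested by a planned comparison, and were picked out because they differed between 5 and 10 min, after their values were seen. On the deposited scale, 5 genes were called at both times against 0 min with opposite signs, higher at 5 and lower at 10 min, and each was also called lower at 10 than at 5 min: sseB (-1.09), pepB (-1.14), iscX (-1.57), fdx (-1.46) and nrdI (-1.09). The fall against 0 min belongs to that scale: at 10 against 0 min all 5 stood above 0 with the stable RNA anchor, median centring and quantile normalization, as for fdx at 0.334, 0.210 and 0.109 and for iscX at 0.374, 0.250 and 0.182. Opposite calls were kept by 3 of the 5 with the ribosomal RNA anchor and by 3 with ribosomal and transfer RNA genes left out. The ferredoxin gene fdx stood at 58.8 ± 8.73, 91.1 ± 23.6 and 31.9 ± 4.47 FPKM at 0, 5 and 10 min (SD, n = 3), and iscX at 51.9 ± 14.3, 86.9 ± 15.1 and 29.2 ± 9.25 FPKM. Both lie at the end of the isc operon for iron-sulfur clusters, whose first gene iscR fell from 166.8 ± 22.1 to 72.7 ± 7.96 FPKM by 5 min. The rise by 5 min was not called without 0 min replicate 1 for iscX (0.61) or fdx (0.49), nor for fdx without 5 min replicate 2 (0.41).

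Against 0 min, the set test pointed up at 5 min and down at 10 min for amino acid synthesis and for fatty acid and phospholipid synthesis, but most of these directions were not called. For amino acid synthesis, the test was called at 5 min (adjusted p = 0.00585; adjusted p = 0.813 with an estimated correlation) and not at 10 min (adjusted p = 0.749). Its median at 10 against 5 min was -0.77, which was called (adjusted p = 4.57e-10; adjusted p = 0.75 with an estimated correlation). For fatty acid and phospholipid synthesis neither time was called (adjusted p = 0.507 and 0.463). Its median at 10 against 5 min was -0.50, or 0.24 with the stable RNA anchor, which was called as deposited (adjusted p = 0.00539; adjusted p = 0.915 with an estimated correlation).

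In data outside the comparisons, 60 values stood beside no gene name in the column of 5 min replicate 2, with a median of 20.6 FPKM (0.0219 to 403). Which genes they belong to is open, and they were not used here.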

How the results depend on the processing

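The ribosomal RNA anchor was chosen after seeing the data, and the other alternatives were planned. Of the values of named genes under the alternatives, 4065 were counted as unchanged, 278 lost a call without turning, 11 gained one and 91 reversed. For lists these numbers were 1865, 81, 59 and 2. A value not called in either setting was counted as unchanged whatever its sign. An example is ompA at 10 against 0 min, at 0.085 as deposited and -0.0074 with the ribosomal RNA anchor. A value that turned and also lost its call was counted as reversed. All 91 reversals of genes came from scalings: 32 with median centring, 31 with the stable RNA anchor, 27 with quantile normalization and 1 with ribosomal and transfer RNA genes left out. Median centring and the anchors shift all genes of a library by the same amount, and their reversals follow from that shift. The cause of other changes was not tested, except where fewer genes or samples entered. The 3 counts of called lists each went to 0 with an estimated correlation. Low depth would weigh most on genes near 1 FPKM, but depth is unknown. In each group below, counts are of genes called unless said otherwise.

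A pseudocount of 0.1 gave a correlation of early and late changes of 0.0418. With a filter at a mean of 10 FPKM, fewer genes were tested. Of these, 1190 were called at 5 against 0 min, 1507 at 10 against 0 min and 1555 at any time. The overlap was then 1106 and the correlation 0.280. With a log2 change of at least 1 as well, the counts were 782, 1655 and 128 for 5 against 0, 10 against 0 and 10 against 5 min, and the overlap 715. Quantile normalization gave 1328, 1580 and 204, 1530 at any time, an overlap of 1147, a correlation of 0.123 and 7 lists at 10 against 5 min. Medians of all genes were then 0.029, 0.046 and 0.014, ribosomal RNAs at 10 against 5 min stood at -0.014 relative to the median gene, and ompA, tufA, rpoB and pnp at 10 against 0 min at -0.44, -0.32, 0.75 and 0.23. Median centring gave 1793 at 10 against 0 min, 237 at 10 against 5 min, 1722 at any time and an overlap of 1274, with medians of 0.13, 0.18 and 0.040. At 10 against 0 min rnpB, ssrA, lpp, ompC, acpP, rpoB, rpoS and pnp then stood at 0.21, 0.59, 0.35, 0.23, 0.75, 1.02, 0.35 and 0.58. The stable RNA anchor gave 1013, 1460 and 366, 1587 at any time and an overlap of 776, with medians of 0.31 at 10 against 0 min and 0.37 at 10 against 5 min, and the same genes at 0.34, 0.71, 0.47, 0.36, 0.87, 1.14, 0.47 and 0.71. Leaving out ribosomal and transfer RNA genes gave 430 at 10 against 5 min and a correlation of 0.138, and rpoB at 0.25. Leaving out each library in turn gave 276 to 1769 at 10 against 5 min, with the extremes without 5 min replicates 1 and 3, and a correlation of 0.0212 to 0.101. Ribosomal proteins at 10 against 5 min then stood 0.16 to 0.29 above the median gene, with the set test pointing down without 5 min replicate 3. A replicate block gave 2199, 3010 and 984, 2947 at any time, an overlap of 2075 and 13, 13 and 12 lists.

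The named members of lists with few changes turned direction as follows. At 10 against 0 min rrfG, rrfE, lepA, prfB, atpC, atpB, cyoA, sucA, sucB, sucC, acnA, codB, codA, pyrC, fhuE, sufS and feoB stood at 0.064, 0.19, 0.18, 0.30, 0.31, 0.42, 0.38, 0.54, 0.30, 0.46, 0.27, 0.11, 0.0034, 0.38, 0.11, 0.051 and 0.51 with quantile normalization, at 0.17, 0.40, 0.34, 0.51, 0.62, 0.62, 0.56, 0.54, 0.35, 0.48, 0.33, 0.12, 0.035, 0.38, 0.44, 0.40 and 0.54 with median centring and at 0.30, 0.53, 0.46, 0.63, 0.74, 0.75, 0.69, 0.67, 0.47, 0.61, 0.45, 0.24, 0.16, 0.51, 0.56, 0.52 and 0.67 with the stable RNA anchor. The genes rrfB, rrfA and atpI stood at 0.012, 0.30 and 0.045 with median centring and at 0.14, 0.43 and 0.17 with the stable RNA anchor, and fusA and rpoA at -0.0033 and -0.0023 with quantile normalization. At 5 against 0 min fusA, tufB, lepA and feoB stood at -0.13, -0.035, 0.0026 and 0.076 with quantile normalization, lepA, atpI, feoB and fhuC at 0.20, 0.19, 0.10 and 0.10 with median centring, and lepA at 0.0035 with the stable RNA anchor. At 10 against 5 min the stable RNA anchor put codB and rpsO at 0.19 and 0.24.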

Other observations

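The 3 patterns weighed below were noticed in these data; the tests of decay alone and of reads shared with cspA were chosen only after their result was seen. The genes in the next paragraph were chosen after their values were seen.

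Some genes peaked at 5 min: 79 were called higher at 5 than at 0 min and lower at 10 than at 5 min, 13 of them transfer RNAs. The 5 min libraries enter both calls with opposite sign, which raises this number, so the 56.2 that independent lists of these lengths would share is no fair measure of chance, and no excess was tested. Among them were 5 of 5 art genes, for arginine uptake, 8 of 9 arginine synthesis genes (argA to argI, without argE), 0 of 2 car genes, 7 of 7 puu genes, for putrescine use, 4 of 4 bet genes, 4 of 5 cyo genes, of the bo oxidase, and 5 of 9 nrd genes, of ribonucleotide reductase. The bet genes serve choline uptake (betT), its conversion to betaine (betA and betB) and their repression (betI). These families were picked after their values were seen and were not tested for enrichment. The gene puuB, of putrescine use, stood at 0.876 ± 0.268, 11.1 ± 1.68 and 3.12 ± 1.16 FPKM at 0, 5 and 10 min (SD, n = 3). At these times betA, choline dehydrogenase, stood at 3.42 ± 0.189, 15.8 ± 2.93 and 6.15 ± 0.280 FPKM. The gene argA, for the first enzyme of arginine synthesis, stood at 5.86 ± 0.247, 21.2 ± 5.30 and 7.04 ± 1.27 FPKM. With the stable RNA anchor 8 genes followed this course, 7 of them among the 79, and 46 of the 79 still went up and then down in value. The ribosomal RNA anchor gave 83 genes (73 of the 79), leaving out ribosomal and transfer RNA genes 47 (43), median centring 49 (23) and quantile normalization 36 (20). The count was 34 without 5 min replicate 1, 35 without 5 min replicate 2, 191 without 5 min replicate 3, 40 without 10 min replicate 1 and 49 without 10 min replicate 3.

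A small set rose between 5 and 10 min, 12 genes as deposited but 2 without 10 min replicate 3, 5 without 5 min replicate 2, 9 without 5 min replicate 1, and 8 without 5 min replicate 3, 10 min replicate 1 or 10 min replicate 2. Of the 12, fepA, entB, efeO and efeB serve iron uptake, and the others were narK, hicA, napF, uraA, metK, phoU, creD and ibsC. The gene creD went from 5.83 ± 0.183 to 18.4 ± 3.25 FPKM (log2 change 1.49, SE 0.19), efeB from 2.78 ± 1.11 to 5.99 ± 0.902 and efeO from 4.99 ± 1.22 to 9.11 ± 1.31. The call of efeB ended without 10 min replicate 3 (0.87), and that of efeO without 5 min replicate 2 (0.74) or 10 min replicate 2 (0.67) or 3 (0.78).

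Messages of ribosomal proteins rose against ribosomal RNA itself. The median log2 ratio of their 54 genes to summed ribosomal RNA was 0.724 at 10 against 0 min (lower quartile 0.457, 51 of 54 above 0), which argues against decay alone of RNA labelled before the chase, unless labelled ribosomal RNA was lost faster than these messages. The ratio was higher at 5 against 0 min, at 0.952 with 54 of 54 above 0, so the rise came by 5 min. Of 1619 other genes with a mean of at least 10 FPKM, 266 stood above 0 at 5 min and 136 at 10 min. For gene length and abundance, 10000 random lists were drawn from the 50 genes nearest in both to each ribosomal protein gene. Their highest median log2 change on the deposited scale was -0.0157, against 0.816 for the ribosomal proteins. How close the matches came was not checked, so length and abundance are argued against only as far as the matches reach. These lists were not compared by the ratio to ribosomal RNA. Scaling between libraries cancels from the ratio to ribosomal RNA. Continued labelling from AzG left in the cells during the chase, new transcription of ribosomal protein genes after the change of medium, and carry-over of unlabelled RNA on the beads may each play a part and were not tested, since no library without AzG was analysed here.

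Genes late in some operons stood higher at 5 min than genes early in them, as in the isc operon, from which the idea came that transcripts begun before the chase were completed, or lost their early parts first. In 38 operons whose gene order had not been examined, the mean rank correlation of gene order with the change at 5 against 0 min was -0.0418 (SE 0.108, sign-flip permutation p = 0.699), so the idea is not borne out as a general pattern but an effect within that error stays open; the planned bound, a missed threshold, was too weak to exclude it. Over all 52 operons the mean was 0.0475 (permutation p = 0.603). With only genes of at least 10 FPKM and no pseudocount the mean was 0.107 over 31 operons (SE 0.113). With the trend on abundance removed it was 0.104 over 52 operons (SE 0.0924), and neither passed the threshold. In the 14 operons examined before, the mean was 0.290 (SE 0.162, sign-flip permutation p = 0.0981), with 8 above 0 and 6 below. Since no pattern over all operons was established, these tests cannot tell whether low values or abundance play a part.

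Of 28 genes of anaerobic respiration and fermentation, 27 had their highest mean at 0 min, right after the 10 min spin (not napF). So had 9 of 9 genes in the list of cold shock proteins. Whether each of these 9 responds to cold was not tested, so their count alone does not speak for cooling. For a return of oxygen to packed cells, 17 genes repressed by ArcA, the regulator of low oxygen, had a median of -0.23 at 5 against 0 min, above 99.18% of random lists matched on expression, which passes the planned bound. For these 17 genes that is a smaller fall than in matched genes and not a rise. Of them, 13 were below 0, 1 was called higher and 2 lower. A mean under 5 FPKM, where the pseudocount shrinks changes, was found for 14, so the idea stays open. The TCA cycle genes called higher at 5 min (9 of 15, with 0 lower) were not among the 17. Nor were the terminal oxidase genes, with 4 higher and 3 lower of 8. For cooling during the spin, 11 cold-inducible genes outside the csp family had a median of -1.26 at 10 against 0 min, at percentile 5.19 of random lists, which misses the planned bound of 5% and leaves it open. Reads of cspA shared with cspB are argued against, since cspB changed by -1.60 (SE 0.189) more than cspA, but for cspG, at 0.191 (SE 0.126) from cspA, shared reads and a shared course cannot be told apart, and other csp genes were not tested. A change in transcription and the decay of labelled messages cannot be separated here, since every library was taken after the spin.

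Other splits of the libraries bear on the counts. Of 10 splits of the 6 libraries compared, 1, the real one, gave as many genes in each comparison: 2135 at 5 against 0 min (highest other 0), 3000 at 10 against 0 min (0) and 851 at 10 against 5 min (1). For called lists, 2, 3 and 2 of 10 splits gave as many, the real counts being 14, 12 and 12 and the highest others 14, 12 and 13. With 10 splits no share under 0.05 can be reached. For lists the limit is not only the number of splits, since wrong splits gave as many calls or, at 10 against 5 min, more. The counts of lists called with the preset correlation therefore do not stand apart from those of other splits. For the test over the 3 times, 100 of the 280 splits were drawn, and 1, the real one, gave as many as 2923 genes (highest other 22). A random assignment of these libraries to the times is thus an unlikely source of that count. This holds only for the spread between these samples, which may be technical, since the labels do not say whether replicates were separate cultures.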
